A study of Mus musculus with 8 samples.

How the data were processed

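RNA was measured on 8 Affymetrix Mouse Gene 1.0 ST arrays, whose transcript clusters gather probes spread along each gene. Per the labels and the series' design text, LSK cells and GMP cells were sorted from the bone marrow of 2 knockout and 2 control mice at 7 weeks of age, on a backcrossed C57BL6 background. About 200000 cells were purified per sample at a purity above 98%. RNA was extracted with a column kit for small samples, amplified with a NuGEN kit (the labels and the design text name it differently) and labelled with biotin. Knockout animals carried Vav1-iCre and 2 floxed Cbfb alleles, and controls the same Cre with 1 floxed and 1 intact allele. Each of the 4 groups (Het LSK, KO LSK, Het GMP, KO GMP) held 2 arrays, assigned from the genotype and cell type in the labels.

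The deposited values are log2 expression values that the authors made with RMA (robust multi-array average), per the submitters' processing notes. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of each transcript cluster. Its software and version, and the genome build behind the clusters, are not given in the sources used here, so no coordinates are printed. RMA gives no detection call, so a level near the lower end is not shown to be expression, and the change of a dim gene is understated. RMA normalization takes the overall distribution as equal in all samples, so a shift of all transcripts together would not be visible. Amplification before labelling can compress or stretch differences between transcripts.

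The table held 35556 rows. The platform's annotation gave exactly 1 gene symbol to 21789 of them (19938 genes), several to 1621 and none to 12146. Rows with several symbols or none entered no reported comparison; they were tested only where all rows of the table were. Of the 21789, 21698 matched a mouse reference table (assembly GRCm38.p6, used for names only) by Entrez number, and 0 symbols changed. For 999 genes there were several rows, 2850 in all. Of these genes, 0 had rows called in opposite directions in the same comparison, except Hmcn1 (77 rows, named after its values were seen) between GMP and LSK in Het. Rows are counted in the totals. For gene lists and named genes, the row with the highest mean over the 8 arrays stood for the gene.

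Differences were tested with limma (version 3.58.1, R 4.3.3): lmFit with 1 mean for each of the 4 groups over all 8 arrays (4 residual degrees of freedom), and eBayes (4.83 prior degrees of freedom), two-sided. The 5 contrasts were KO against Het in LSK and in GMP, the interaction (the GMP effect minus the LSK effect), and GMP against LSK in Het and in KO. P-values were adjusted by Benjamini-Hochberg over the 21789 rows of each contrast, and a row passed at an adjusted p under 0.05. SE is limma's standard error of a difference, which is equal for the LSK and the GMP comparison of a gene.

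The 25 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, on 1 row per gene, with Benjamini-Hochberg adjustment over the lists; a list that passed is said to be called. Alternatives were an estimated correlation and limma's fry. The lists covered core-binding factor subunits and cofactors, described RUNX target genes, stem cell genes, Hox genes and cofactors, lymphoid priming, megakaryocyte and platelet, erythroid, primary granule and secondary granule genes, monocyte, macrophage and dendritic cell genes, mast cell, basophil and eosinophil genes, B cell, T and NK cell, and endothelial and stromal genes. The others were cell cycle, cyclin D genes and CDK inhibitors, Fanconi anemia and homologous recombination, p53 response and apoptosis, interferon response, cytokine receptors and signalling, adhesion, homing and chemokine, hematopoietic transcription factors, ribosome biogenesis, ribosomal proteins, and immediate early and heat shock genes. Lists share members: 4 of the 20 measured megakaryocyte genes, 6 of 26 lymphoid priming genes and 19 of 37 transcription factors also stood in another list. In Het LSK, 24 of the 26 lymphoid priming genes and 14 of the 20 megakaryocyte genes lay above the median of the tested rows, and in Het GMP 13 and 13.

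The groups, contrasts, tests, thresholds, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the members of the core-binding factor list, the 10 largest rises and 10 largest falls per KO against Het contrast, the 5 largest each way per other contrast, and up to 4 called members per list, or the 2 largest differences where none was called. The largest rises and falls were taken among rows that passed and in which both arrays of one group lay beyond both of the other. Predicted or unnamed genes were only counted (96 of the called rows in LSK and 51 in GMP). Not all the genes it took are printed. Examples for called lists were chosen after the leave-one-out results were seen and favour members that kept their calls, and those for lists without a call are not always the largest. Of all the calls the rule named, 67 of 87 in LSK, 60 of 81 in GMP and 39 of 61 in the interaction were kept with each array left out in turn, as were 72 of 86 between GMP and LSK in Het and 41 of 62 in KO.

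The alternatives were other filters on dim rows, all rows of the table, another quantile normalization, subtraction of array medians, a variance trend, robust fitting, array weights, fits of the 2 groups alone, blocks by replicate number, other thresholds and a fold minimum, and leaving out each array. One row per gene was added after the data were seen. The procedure was tested on simulated data for the LSK comparison, with 100 rows changed per fold size in each of 5 simulations over 21789 rows. It recovered 94.2% of 2-fold and 100% of 4-fold changes, with 6.59% of calls false. A list of 25 genes shifted by 0.5 was called in 5 of 5 simulations over 19938 genes, and 0 of 120 unshifted lists were, by limma's camera. The rows were simulated independently and the list members drawn at random. The simulation therefore cannot show how the list test behaves where the genes of a list vary together. Further software was statmod 1.5.0, data.table (version 1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.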

Results

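Gene expression was measured in mouse bone marrow progenitors with a Cre-driven deletion of Cbfb and in a heterozygous control. Cbfb is the gene for the partner subunit that stabilises Runx transcription factors on DNA. In the knockout (KO), both Cbfb alleles were floxed and a Vav1-driven Cre recombinase, active in blood cells, was present. The control (Het) carried the same Cre with 1 floxed and 1 intact allele. No wild type was measured. Each effect is therefore that of KO against Het, also where it is called Cbfb loss. LSK cells, the fraction that holds stem cells and multipotent progenitors, and GMP cells, the granulocyte and macrophage progenitors, were sorted from 2 mice of each genotype. This gave 4 groups (Het LSK, KO LSK, Het GMP, KO GMP) of 2 arrays each. Values below are log2 expression values, given as mean ± SD over 2 arrays, and differences are on the log2 scale. Array medians lay between 4.63 and 4.74 over all rows of the table. Over the rows with 1 gene symbol they lay between 4.92 and 5.09, and those medians were the ones subtracted where the text says so. Across the 21789 rows that carry 1 gene symbol, arrays of the same group correlated at 0.990 to 0.995 and arrays of different groups at 0.955 to 0.983. The first principal component held 47.5% of the variance and ran from KO LSK (-41.3 and -32.8) through Het LSK (-22.0 and -25.8) and KO GMP (12.2 and 10.3) to Het GMP (51.0 and 48.4). The labels call the arrays of a group biological replicates and do not tie single arrays to single mice, so the p-values measure the spread between these arrays. Their number limits the precision: an exact two-sided permutation of 2 against 2 arrays cannot go below p = 0.333, and all p-values below are limma's, adjusted by Benjamini-Hochberg.

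The targeted gene and its partners came first. Cbfb (transcript cluster 10574632) stood at 7.59 ± 0.09 in Het GMP and 6.72 ± 0.34 in KO GMP and fell by 0.86 (SE 0.16, adjusted p = 0.013). In LSK it stood at 7.56 ± 0.01 in Het and 6.96 ± 0.04 in KO, a difference of -0.60 (SE 0.16) that missed the threshold (adjusted p = 0.0557). Both KO arrays lay below both Het arrays in each cell type. Runx1 (transcript cluster 10441003), which encodes the main DNA-binding partner of Cbfb in blood progenitors, rose in both: from 9.11 ± 0.03 to 10.64 ± 0.34 in LSK (1.53, SE 0.16, adjusted p = 0.000448) and from 8.72 ± 0.04 to 10.19 ± 0.06 in GMP (1.47, SE 0.16, adjusted p = 0.000694). Runx3 rose by 0.50 in GMP (adjusted p = 0.0382) and differed by 0.20 in LSK (adjusted p = 0.404). Cbfa2t2 (-0.24 in LSK, 0.20 in GMP), Cbfa2t3 (0.18, 0.82) and Runx1t1 (-0.22, 0.08), all corepressor genes, did not pass (Cbfa2t3 in GMP passed without either KO LSK array, adjusted p = 0.0402), and Runx2 was not analysed here. Of the 6 measured members of this list, 1 rose and 0 fell in LSK, and 2 rose and 1 fell in GMP; adjusted over the list alone, 1 rose and 1 fell in LSK and 3 rose and 1 fell in GMP. The list was called in GMP (adjusted p = 0.0391, and adjusted p = 0.366 with an estimated correlation) and not in LSK (adjusted p = 0.805).

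The Cbfb values rest on few arrays. Its GMP call was lost without Het GMP replicate 1 (adjusted p = 0.0689), Het GMP replicate 2 (0.104) or KO GMP replicate 1 (0.0755), and when all rows of the table were tested (0.0632); in LSK it passed without either KO GMP array (0.0252). The Runx3 call in GMP was lost without either Het LSK array (0.0583), Het GMP replicate 1 (0.109) or 2 (0.232), or KO GMP replicate 1 (0.142) or 2 (0.228), and the list call in GMP without Het GMP replicate 1 (0.158) or KO GMP replicate 2 (0.150). The deleted part of Cbfb is not given in the sources used here, and probes outside it check nothing. The Cbfb signal in KO stayed above the array medians in both cell types. How complete the deletion was in the sorted cells cannot be told from it.

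**Figure D1:**
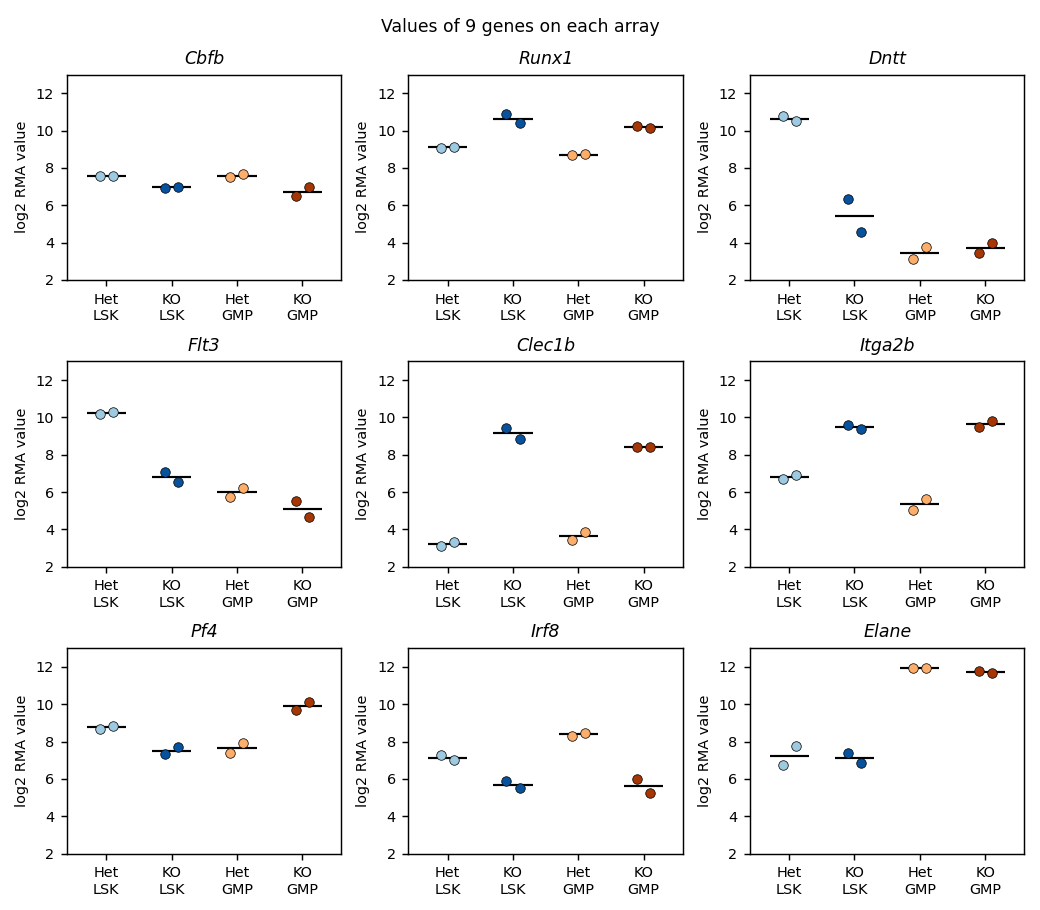
Log2 expression (y axis) of single genes on each array, with the 4 groups along the x axis; each point is 1 array and each bar the mean of 2 arrays. Clec1b stands at 3.24 ± 0.15 in Het LSK and 9.15 ± 0.42 in KO LSK, and Dntt at 10.63 ± 0.21 and 5.45 ± 1.25.

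The next comparison asked what the loss of Cbfb changed in LSK cells. By limma's list test with a preset correlation, lymphoid priming genes were lower in KO LSK and genes of platelets and their precursors were higher. With an estimated correlation 0 lists were called. Clec1b, a receptor of platelets and megakaryocytes, rose by 5.91, from 3.24 ± 0.15 to 9.15 ± 0.42 (SE 0.21, adjusted p = 1.24e-05). Dntt, the terminal deoxynucleotidyl transferase of early lymphoid cells, fell by 5.19, from 10.63 ± 0.21 to 5.45 ± 1.25 (SE 0.49, adjusted p = 0.000259). In all, 1684 of 21789 tested rows passed, 657 higher and 1027 lower in KO.

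The genes with the largest rises after Clec1b were Fgf10, a growth factor (4.92, SE 0.26), Kcnk9, a potassium channel gene (4.64, SE 0.35), the paired receptor genes Cd200r4 (4.58, SE 0.24) and Cd200r3 (4.17, SE 0.32), the chemokine receptor gene Cxcr2 (4.31, SE 0.23), the mast cell protease gene Cpa3 (3.92, SE 0.23), Kcnj5 (3.92, SE 0.31), Dlk1 (3.87, SE 0.25) and Jam3 (3.85, SE 0.19). The chemokine gene Ccl3 fell by 5.32 (SE 0.36, adjusted p = 5.6e-05). Lsp1 fell by 4.21 (SE 0.22), Emb fell by 4.17 (SE 0.19) and Lgals1 fell by 3.95 (SE 0.34). B3gnt5 fell by 3.74, Atp8b4 fell by 3.65, Dpp4 fell by 3.62, Vpreb1, a surrogate light chain gene of early B cells, fell by 3.60, and Nkg7 fell by 3.56. All 20 kept their calls with each array left out in turn.

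Of the 26 measured lymphoid priming genes, 20 fell and 0 rose in KO LSK (21 fell and 0 rose adjusted over the list alone), with a list median of -1.59. Besides Dntt and Lsp1, Ebf1, a transcription factor of B cell commitment, fell by 3.42 (SE 0.21, adjusted p = 3.42e-05), and Flt3, a cytokine receptor of lymphoid-primed progenitors, fell by 3.41 (SE 0.28, adjusted p = 0.000146). The list test gave adjusted p = 5.13e-22, and adjusted p = 0.124 with an estimated correlation. Of 16 B cell genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.79). Vpreb3 fell by 3.47 (SE 0.23) and Cd79a, a signalling chain of the B cell receptor, fell by 3.05 (SE 0.17). This list gave adjusted p = 3.63e-08, and adjusted p = 0.0817 with an estimated correlation. Of 25 T and NK cell genes, 5 fell and 3 rose (10 and 3 adjusted over the list alone), in both directions: Thy1 fell by 3.01 and Klrd1 fell by 2.37, while Lat, an adaptor of T cell receptor signalling, rose by 1.42. Here adjusted p = 0.000837, and adjusted p = 0.124 with an estimated correlation.

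Of 20 megakaryocyte and platelet genes, 11 rose and 1 fell in KO LSK (14 and 2 adjusted over the list alone), with a median of 0.91. Treml1 rose by 3.04 (SE 0.23), Gp5, part of the von Willebrand factor receptor, from 6.80 ± 0.25 to 9.80 ± 0.11 and Itga2b, the integrin chain CD41, by 2.68 (SE 0.20). The member that fell was Pf4, a chemokine of platelet granules, from 8.76 ± 0.11 to 7.51 ± 0.26 (adjusted p = 0.0094); this call was lost without Het LSK replicate 2 (adjusted p = 0.0707). The list test gave adjusted p = 1.66e-10, and adjusted p = 0.373 with an estimated correlation. Stem cell genes moved both ways, with 5 up and 7 down of 27 (7 and 10 adjusted over the list alone), and the list was not called (adjusted p = 0.493). The surface receptor genes Tek (2.48, SE 0.16) and Slamf1 (2.40, SE 0.24) rose, while Mecom, a transcription factor of stem cells, fell by 2.47 (SE 0.26) and Procr fell by 2.27 (SE 0.23). In the mast cell, basophil and eosinophil list, 6 of 22 rose and 1 fell (7 and 2 adjusted over the list alone), without a call (adjusted p = 0.17): Cpa3 and Hdc, the histidine decarboxylase gene (2.38), rose, and Mcpt8, a basophil protease gene, fell by 1.69.

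Of 30 monocyte, macrophage and dendritic cell genes, 10 fell and 1 rose in KO LSK (14 and 1 adjusted over the list alone; median -0.43), among them Cd74, the invariant chain of antigen presentation, which fell by 3.41 (SE 0.26), and Ly86, which fell by 3.26 (SE 0.57) and lost its call without Het LSK replicate 1 (adjusted p = 0.0713). The list gave adjusted p = 1.08e-05, and adjusted p = 0.436 with an estimated correlation. Of 20 primary granule genes, 6 fell and 2 rose (8 and 4 adjusted over the list alone; adjusted p = 0.00495, and adjusted p = 0.453 with an estimated correlation): Clec12a fell by 2.32, and Cst7 rose by 1.28. The call was lost without Het LSK replicate 2 (adjusted p = 0.0667) or KO LSK replicate 2 (0.0541). Of 26 interferon response genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.28), with adjusted p = 0.000837, and adjusted p = 0.745 with an estimated correlation. Ifit3 fell by 1.60 (SE 0.18), and Iigp1 fell by 1.00 with a call that was lost without Het LSK replicate 1 (adjusted p = 0.0569). The interferon list call was lost without Het LSK replicate 1 (adjusted p = 0.0642) or KO LSK replicate 2 (0.140).

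Of 23 immediate early and heat shock genes, 3 rose and 0 fell in KO LSK (9 and 0 adjusted over the list alone; median 0.38; adjusted p = 6.32e-05, and adjusted p = 0.453 with an estimated correlation). Btg2 rose by 1.01 and Klf2 by 0.73; both calls were lost without Het LSK replicate 1 (adjusted p = 0.114 and 0.0885) or KO LSK replicate 1 (0.0624 and 0.0528). No cell cycle gene of 37 passed (0 also adjusted over the list alone, 1 lower at an unadjusted p under 0.05), and the largest difference was that of Cenpf (-0.56), which depended on the KO arrays: it was -0.090 without KO LSK replicate 1 and -1.03, with a call (adjusted p = 0.00375), without KO LSK replicate 2. The limma list test still called a downward shift of the list (median -0.22, and -0.13 after array medians were subtracted; adjusted p = 0.0206, and adjusted p = 0.943 with an estimated correlation), which was lost without Het LSK replicate 1 (adjusted p = 0.325).

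The other lists in LSK were not called. The list test asks for a shift one way, so a list whose genes moved both ways can stay uncalled although its genes changed. Among all 19938 genes, 1558 passed in LSK. Of 23 described RUNX target genes, 3 rose and 4 fell (5 and 7 adjusted over the list alone; adjusted p = 0.667), with Itga2b and Ebf1 the largest changes. Of 19 Hox genes and cofactors, 1 rose and 4 fell (1 and 6; adjusted p = 0.0639): the cofactor gene Pbx3 rose by 1.09 and Hoxa5 fell by 1.22. Of 21 erythroid genes, 2 rose and 3 fell (3 and 6; adjusted p = 0.533), and the carbonic anhydrase genes Car1 and Car2 fell by 3.51 and fell by 1.76. Of 22 secondary granule genes, 3 rose and 2 fell (3 and 3; adjusted p = 0.667), led by Cxcr2 and by Retnlg, which rose by 2.42. Of 37 hematopoietic transcription factors, 4 rose and 9 fell (5 and 10; adjusted p = 0.667): Id1 rose by 1.87 and Id2 fell by 2.16. Of 29 cytokine receptor and signalling genes, 2 rose and 4 fell (4 and 9; adjusted p = 0.26), led by Flt3 and Il7r, and of 28 adhesion, homing and chemokine genes 5 rose and 5 fell (8 and 7; adjusted p = 0.667), led by Ccl3 and Cxcr2. Of 21 endothelial and stromal genes, 2 rose and 3 fell (4 and 3; adjusted p = 0.934), and Pdgfrb fell by 2.69 and Bgn fell by 1.56. Of 11 cyclin D genes and CDK inhibitors, 1 rose and 2 fell (4 and 3; adjusted p = 0.745): Ccnd1 fell by 1.68 and Ccnd2 fell by 1.13. Of 22 p53 response genes 1 rose and 1 fell (1 and 1; adjusted p = 0.934), and of 29 Fanconi anemia and homologous recombination genes 1 rose and 0 fell (1 and 0; adjusted p = 0.817). No ribosome biogenesis gene of 33 and no ribosomal protein gene of 34 passed limma's test (0 also adjusted over the list alone; 1 and 0 of them lower at an unadjusted p under 0.05, none higher), and both list tests gave adjusted p = 0.667. Calls were lost for Pbx3 without Het LSK replicate 1 (adjusted p = 0.0511), for Hoxa5 without Het LSK replicate 2 (0.0644) and for Retnlg without KO LSK replicate 2 (0.0595).

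By limma's camera test with a preset correlation, 9 of the 25 lists were called in LSK, 2 up and 7 down. With an estimated correlation 0 were (3 at an unadjusted p under 0.05), while limma's fry, which asks only whether a list's genes move one way, called 6. Median, mean and test differed in sign for 7 lists, none of them called. At a 2-fold minimum, 293 rows were higher and 438 lower. The split between higher and lower depends on the scaling: 39.0% of the called rows were higher in KO as deposited, and 52.4% (903 of 1724) after each array's median was subtracted. Without Het LSK replicate 1 the count was 1008 and without replicate 2 it was 994. In 45.5% of rows the 2 groups did not overlap, where chance gives 33.3%.

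**Figure D2:**
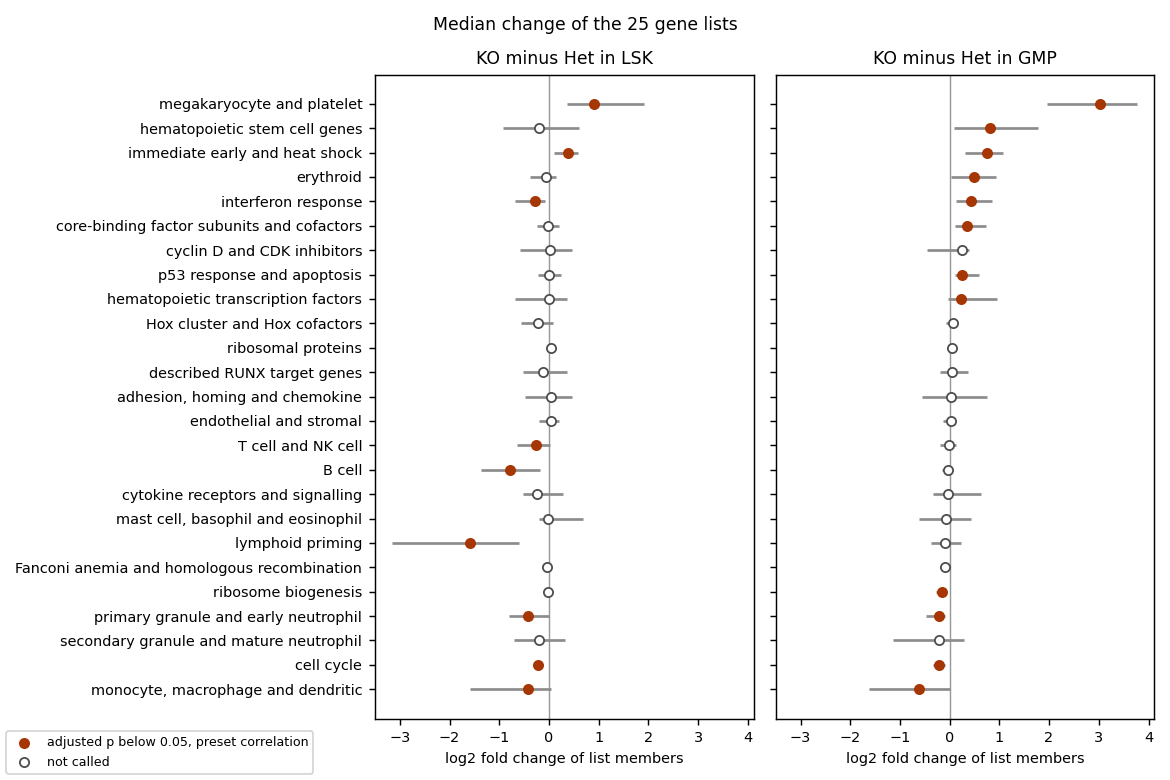
Median log2 difference between KO and Het (x axis) over the measured members of each of 25 gene lists (y axis), in LSK (left) and GMP (right); bars span the quartiles of the members, and filled points mark lists called with a preset correlation. The lymphoid priming list lies at -1.59 in LSK and -0.09 in GMP, and the megakaryocyte and platelet list at 0.91 in LSK and 3.03 in GMP.

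In GMP cells the comparison of KO with Het asked the same question in cells committed to the granulocyte and macrophage lineages. By limma's list test with a preset correlation, the megakaryocyte, the stem cell and the immediate early and heat shock lists were among those higher in KO GMP. The list of monocyte, macrophage and dendritic cell genes was among those lower. With an estimated correlation 0 lists were called. Clec1b rose by 4.78, from 3.65 ± 0.29 to 8.43 ± 0.02 (SE 0.21, adjusted p = 1.59e-05). Ly86, a cell surface gene of monocytes and B cells, fell by 4.37, from 9.22 ± 0.15 to 4.85 ± 1.54 (SE 0.57, adjusted p = 0.00197). In all, 1312 of 21789 rows passed, 752 higher and 560 lower in KO.

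The largest rises after Clec1b were those of Clca3a1 (4.53, SE 0.27), the thrombin receptor gene F2r (4.45, SE 0.18), Gp5 (4.44, SE 0.16), Mtss2 (4.28, SE 0.31), Itga2b (4.28, SE 0.20), Mmrn1, which encodes multimerin of platelet granules (4.19, SE 0.21), the kinase gene Prkcq (4.12, SE 0.17), Treml1 (3.98, SE 0.23) and Kcnj5 (3.87, SE 0.31). Among the genes that fell, Ly6a2 fell by 4.30 (SE 0.47), Ak4 fell by 3.95 (SE 0.27), Aoah fell by 3.75 (SE 0.25), B3gnt5 fell by 3.45 (SE 0.22) and Sorl1 fell by 3.37 (SE 0.16). Lgals1 fell by 3.32, Met, the hepatocyte growth factor receptor gene, fell by 3.04, S1pr3 fell by 2.99 and Gpr141 fell by 2.98. These 20 genes also kept their calls with each array left out in turn.

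Of 20 megakaryocyte and platelet genes, 17 rose and 0 fell in KO GMP (18 and 0 adjusted over the list alone), with a median of 3.03. The list gave adjusted p = 2.27e-35, and adjusted p = 0.203 with an estimated correlation. Of 21 erythroid genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.49). The transcription factor gene Gata1 rose by 2.13 (SE 0.18), its cofactor Zfpm1 by 2.33 (SE 0.14) and the water channel gene Aqp1 by 2.99 (SE 0.24), while the carbonic anhydrase gene Car1 fell by 2.75 (SE 0.42). The erythroid list gave adjusted p = 6.54e-07, and adjusted p = 0.265 with an estimated correlation. Of 27 stem cell genes, 14 rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.82. In Het GMP 12 of the 27 lay above the median of the tested rows, and a gene near the floor cannot be seen to fall. Slamf1 rose by 3.42 (SE 0.24), Tek by 3.25 (SE 0.16), the homeobox gene Meis1 by 3.11 (SE 0.22) and Esam by 2.67 (SE 0.19). The stem cell list gave adjusted p = 2.12e-13, and adjusted p = 0.265 with an estimated correlation.

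Of 23 immediate early and heat shock genes, 12 rose and 0 fell in KO GMP (17 and 0 adjusted over the list alone; median 0.74), with adjusted p = 2.67e-13, and adjusted p = 0.265 with an estimated correlation. Egr1 rose by 3.24 (SE 0.24), Fosb by 1.40 (SE 0.22) and Btg2 by 1.39 (SE 0.20). Of 26 interferon response genes, 8 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.42), with adjusted p = 2.48e-06, and adjusted p = 0.458 with an estimated correlation. Oas2 rose by 1.47 and Rtp4 by 1.41, with calls that were lost without Het GMP replicate 2 (adjusted p = 0.0614 and 0.0533); that of Rtp4 was also lost without KO GMP replicate 1 (0.0518). Of 37 hematopoietic transcription factors, 9 rose and 2 fell (16 and 5 adjusted over the list alone; median 0.23; adjusted p = 0.000127, and adjusted p = 0.366 with an estimated correlation). Of 22 p53 response and apoptosis genes, 4 rose and 0 fell (6 and 3 adjusted over the list alone; median 0.25; adjusted p = 0.00102, and adjusted p = 0.265 with an estimated correlation). They included Trp53inp1, from 5.43 ± 0.11 to 6.93 ± 0.02, and Bcl2l1, which encodes the survival protein Bcl-xL (1.35, SE 0.13).

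Of 30 monocyte, macrophage and dendritic cell genes, 12 fell and 1 rose in KO GMP (16 and 2 adjusted over the list alone; median -0.62). Irf8, a transcription factor of monocyte and dendritic cell development, fell by 2.74 (SE 0.24, adjusted p = 0.000258), and H2-Aa, an MHC class II chain, fell by 2.07 (SE 0.23). The list gave adjusted p = 5.62e-07, and adjusted p = 0.272 with an estimated correlation. Of 20 primary granule genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.21; adjusted p = 0.00208, and adjusted p = 0.366 with an estimated correlation), led by Nkg7, which fell by 1.41 (SE 0.20). Elane, the neutrophil elastase gene, stood at 11.94 ± 0.01 in Het and 11.73 ± 0.05 in KO and did not pass (adjusted p = 0.8). Of 33 ribosome biogenesis genes, 1 fell and 0 rose (0 and 0 adjusted over the list alone, 7 lower at an unadjusted p under 0.05; median -0.16; adjusted p = 0.000363, and adjusted p = 0.6 with an estimated correlation). This was Nolc1, which fell by 0.60 (adjusted p = 0.0478) and lost its call without Het LSK replicate 1 or 2 (both 0.0765), Het GMP replicate 1 (0.259) or 2 (0.165), or KO GMP replicate 1 (0.266) or 2 (0.138). No cell cycle gene of 37 passed (0 also adjusted over the list alone, 2 lower at an unadjusted p under 0.05; Aurkb differed by -0.55). The limma list test called a downward shift (median -0.22, adjusted p = 0.0109, and adjusted p = 0.788 with an estimated correlation), which was lost without KO GMP replicate 1 (adjusted p = 0.427).

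The lymphoid priming list was not called in GMP (median -0.09, adjusted p = 0.598), with 4 members up and 3 down of 26 (5 and 5 adjusted over the list alone). The interleukin 7 receptor gene Il7r rose by 2.03 (SE 0.27) and Foxo1 by 1.77 (SE 0.15), and Notch1 fell by 1.44 (SE 0.14). The remaining lists were not called, which again does not show that genes moving both ways were unchanged. Among all 19938 genes, 1231 passed in GMP. Of 23 described RUNX target genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone; adjusted p = 0.059), led by Itga2b and Prkcq. Of 19 Hox genes and cofactors, 2 rose and 0 fell (2 and 0; adjusted p = 0.138): Meis1 and Pbx3 (1.23). Of 22 secondary granule genes, 3 rose and 4 fell (3 and 7; adjusted p = 0.351), and Retnlg rose by 2.46 and Cxcr2 by 2.37; the call of Retnlg was lost without Het GMP replicate 1 (adjusted p = 0.141), KO GMP replicate 1 (0.0551) or KO GMP replicate 2 (0.118). Of 22 mast cell, basophil and eosinophil genes, 2 rose and 5 fell (4 and 5; adjusted p = 0.26): Ms4a2, a chain of the IgE receptor, fell by 1.90 and Mcpt8 fell by 1.84.

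Of 16 B cell genes, 0 rose and 1 fell in GMP (0 and 1 adjusted over the list alone; adjusted p = 0.793): Cd72 fell by 0.69. Of 25 T and NK cell genes, 2 rose and 0 fell (2 and 0; adjusted p = 0.533): Lat rose by 3.57 and Gata3 by 1.11. In Het GMP only 2 of the 16 B cell genes and 3 of the 25 T and NK cell genes lay above the median of the tested rows. Falls of the others could hardly be seen. Of 21 endothelial and stromal genes, 3 rose and 1 fell (3 and 2; adjusted p = 0.351): Emcn rose by 2.36 and Kdr by 2.22. Of 11 cyclin D genes and CDK inhibitors, 0 rose and 2 fell (5 and 3; adjusted p = 0.537): Ccnd1 fell by 0.85 and Ccnd2 fell by 0.75. Of 29 cytokine receptor and signalling genes, 6 rose and 3 fell (9 and 7; adjusted p = 0.26), among them Cish (1.54), and of 28 adhesion, homing and chemokine genes 6 rose and 4 fell (10 and 8; adjusted p = 0.279), among them Rgs1 (3.30) and S1pr1 (2.59). Of 29 Fanconi anemia and homologous recombination genes 1 rose and 0 fell (1 and 0; adjusted p = 0.351), and no ribosomal protein gene of 34 passed (0 also adjusted over the list alone and, by limma, at an unadjusted p under 0.05; list test adjusted p = 0.279). The call of Cd72 was lost without either Het LSK array (adjusted p = 0.0518), Het GMP replicate 2 (0.214), or KO GMP replicate 1 (0.135) or 2 (0.188). That of Ccnd2 was lost without Het GMP replicate 1 (0.0779) or KO GMP replicate 1 (0.0617).

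With a preset correlation 12 of the 25 lists were called in GMP, 8 up and 4 down; with an estimated one 0 were (4 at an unadjusted p under 0.05), and fry called 8. Median, mean and test differed in sign for 3 lists, none of them called. At a 2-fold minimum, 386 rows were higher and 234 lower. Of the called rows, 57.3% were higher in KO GMP as deposited, but 697 of 1393 after array medians were subtracted, so the lean towards higher rows depends on the scaling. The count was 637 without Het GMP replicate 1, 723 without Het GMP replicate 2, 805 without KO GMP replicate 1 and 634 without KO GMP replicate 2, and 784 when all rows of the table were tested. In 51.3% of rows the 2 groups did not overlap, where chance gives 33.3%.

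The effects of Cbfb loss in LSK and GMP overlapped. Counted once per gene, 303 of 19938 genes were higher in KO in both cell types, where independent lists of the same lengths give 21.0, and 250 were lower in both, against 25.5. Clec1b, Gp5, Itga2b and Runx1 were among those that rose in both, and Lgals1, B3gnt5 and Ly86 among those that fell in both, Ly86 in LSK without a call when Het LSK replicate 1 was left out (adjusted p = 0.0713). Against 15.8 for independent lists, 3 genes were higher in LSK and lower in GMP, and 22 were lower in LSK and higher in GMP (33.9). The latter included Pf4, which rose from 7.68 ± 0.39 to 9.91 ± 0.33 in GMP (2.23, SE 0.22, adjusted p = 0.000488) after its fall in LSK, a fall whose call was lost without Het LSK replicate 2 (adjusted p = 0.0707). The 3 genes, named after their values were seen, were Tifab (1.17 in LSK, -0.86 in GMP), Fkbp1b (0.62, -0.91) and Catspere2 (0.55, -0.70). In LSK the call of Fkbp1b was lost without Het LSK replicate 1 (0.143) or 2 (0.0573) or KO LSK replicate 2 (0.0920), and in GMP that of Tifab without Het GMP replicate 1 (0.158) or 2 (0.137) or KO GMP replicate 2 (0.202). Catspere2 lost its call in LSK without Het LSK replicate 1 (0.0908) or 2 (0.162), KO LSK replicate 1 (0.0617) or 2 (0.0942) or either Het GMP array (0.0591), and in GMP without Het GMP replicate 1 (0.0779) or 2 (0.0857) or KO GMP replicate 2 (0.113). The overlap in the same direction was 590 rows; it was 387 without Het LSK replicate 1, 321 without Het GMP replicate 1, 354 without Het GMP replicate 2, 346 without KO GMP replicate 2, and 324 when all rows of the table were tested. The 2 comparisons share no array, but LSK and GMP cells came from the same 2 mice of each genotype. A difference between these mice therefore enters both. Both comparisons also use 1 estimate of the spread per gene, so a gene with a small estimate tends to pass in both. The numbers for independent lists leave this out. A shared spread does not favour 1 direction, and the counts in opposite directions lay below those numbers.

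**Figure D3:**
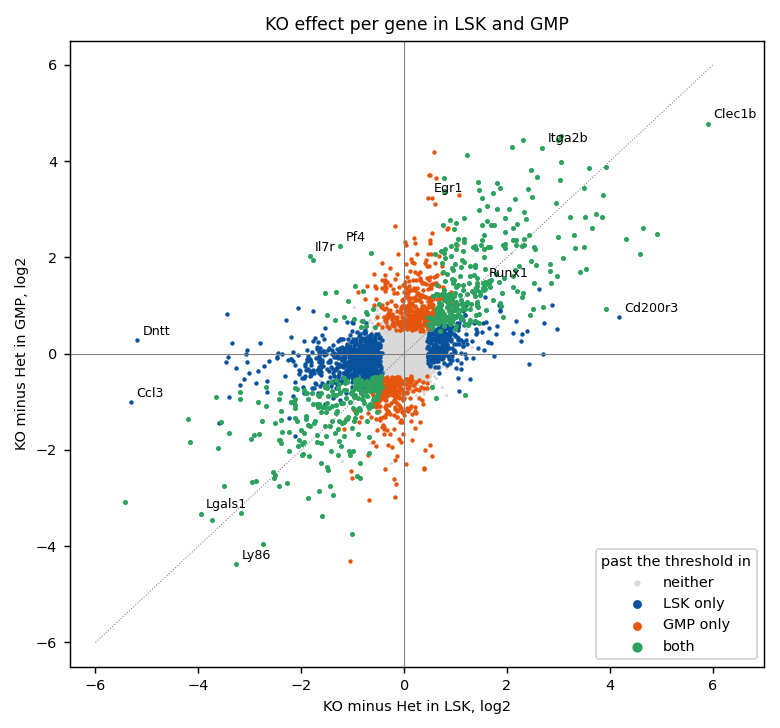
Log2 difference between KO and Het in LSK (x axis) and in GMP (y axis); each point is 1 gene, coloured by whether it passed the threshold in LSK, in GMP, in both or in neither, and the dotted line marks equal differences. Clec1b lies at 5.91 and 4.78, and Dntt at -5.19 and 0.28; a gene past the threshold in 1 cell type is not thereby shown to differ between them.

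Whether the effect of Cbfb loss differed between the cell types was tested with the interaction of genotype and cell type. The effect differed for 499 rows, with 368 more positive in GMP and 131 more positive in LSK. Dntt had the largest difference (5.47, adjusted p = 0.00583) and stood near the floor in GMP of both genotypes (3.45 ± 0.49 in Het, 3.72 ± 0.36 in KO). Ccl3 (4.30, adjusted p = 0.00466) and Wfdc17 (4.27, adjusted p = 0.00583) followed. Il7r (3.86) and Pdzk1ip1 (3.71) changed in opposite directions: Il7r fell by 1.84 in LSK and rose by 2.03 in GMP, and Pdzk1ip1 fell by 1.77 in LSK and rose by 1.95 in GMP. The effects were more positive in LSK for Cd200r3 (-3.41, adjusted p = 0.00665), Ly6a2 (-3.24, adjusted p = 0.046), Cpa3 (-2.99), Gpr141 (-2.80) and Aoah (-2.74). In Het LSK, Gpr141 (2.75 ± 0.23), Aoah (4.22 ± 0.33) and Ly6a2 (4.28 ± 1.15) lay below the median of the tested rows (5.08). They had little room to fall in LSK, so the floor limits their differences. The call of Ly6a2 was lost without any of 6 arrays: Het LSK replicate 1 (0.052), KO LSK replicate 1 (0.0786) or 2 (0.0777), Het GMP replicate 1 (0.142) or 2 (0.158), or KO GMP replicate 2 (0.149).

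By list, the effect was more positive in GMP for lymphoid priming (15 of 26 members, 20 adjusted over the list alone; median 1.57; adjusted p = 2.28e-23, and adjusted p = 0.0898 with an estimated correlation) and for megakaryocyte and platelet genes (10 of 20, 16 adjusted over the list alone with 1 the other way; median 1.45; adjusted p = 3.66e-18, and adjusted p = 0.115 with an estimated correlation). It was also more positive there for stem cell genes (8 of 27, 21 adjusted over the list alone; median 1.07; adjusted p = 1.43e-20, and adjusted p = 0.115 with an estimated correlation) and interferon response genes (7 of 26, 13 adjusted over the list alone; median 0.83; adjusted p = 8.45e-13, and adjusted p = 0.165 with an estimated correlation). The floor of the arrays limits these differences, since a gene near it in Het GMP cannot be seen to fall there. Of the 26 lymphoid priming genes, 24 lay above the median of the tested rows in Het LSK and 13 in Het GMP, where Ebf1 stood at 3.01 ± 0.18, Cd79a at 3.14 ± 0.10 and Klrd1 at 2.71 ± 0.21. The mast cell, basophil and eosinophil list went the other way (5 of 22 more positive in LSK, 7 adjusted over the list alone with 1 the other way; adjusted p = 7.86e-05, and adjusted p = 0.165 with an estimated correlation). The preset correlation called 15 lists, 13 of them more positive in GMP; the estimated one called 0 (6 at an unadjusted p under 0.05) and fry 13. Subtracting array medians moved the share of rows more positive in GMP from 73.7% to 58.4% (275 of 471) and the median of all rows from -0.02 to -0.16, a shift smaller than the medians of the lists named here; the mast cell list moved with it (-0.30 as deposited, -0.44 after subtraction). The count of rows was 294 without Het LSK replicate 2, 223 without Het GMP replicate 1, 250 without Het GMP replicate 2, 308 without KO GMP replicate 1, 258 without KO GMP replicate 2 and 182 when all rows of the table were tested.

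In the control, the comparison of GMP with LSK served as a reference for cell identity. Genes of granulocyte progenitors were higher in GMP: Ms4a3, a gene of granulocyte and monocyte progenitors, by 4.97 (11.76 ± 0.04 against 6.80 ± 0.36, adjusted p = 2.32e-06), Elane by 4.69, Mgam by 4.63, Sgms2 by 4.51 and Fcgr3 by 4.43. Of 20 primary granule genes, 17 were higher and 0 lower, with the same counts adjusted over the list alone (median 2.76; adjusted p = 2.38e-20, and adjusted p = 0.0422 with an estimated correlation). In the other direction, Dntt was lower in GMP by the largest difference (-7.19, adjusted p = 2.71e-05), followed by Wfdc17 (-5.44), Gimap6 (-5.15), Flt3 (-4.25) and Emcn (-3.93). The lists of lymphoid and stem cell genes were lower in GMP. Stem cell genes were lower for 23 of 27 (25 adjusted over the list alone; median -1.83; adjusted p = 6.79e-21, and adjusted p = 0.109 with an estimated correlation), and lymphoid priming genes for 22 of 26 (23 adjusted over the list alone; median -1.87; adjusted p = 1.27e-20, and adjusted p = 0.0857 with an estimated correlation). In all, 3813 rows passed, 1721 higher and 2092 lower in GMP; after array medians were subtracted 4772 passed, with 67.1% higher against 45.1% as deposited. The count was 2223 without Het LSK replicate 2, 2078 without Het GMP replicate 1 and 2367 without Het GMP replicate 2. Of the 25 lists, 20 were called, 6 up and 14 down; 3 held with an estimated correlation (primary granule, B cell, T and NK cell), and fry called 19. Of these 20 lists, cyclin D genes and CDK inhibitors changed the sign of their median with the scaling, from -0.06 as deposited to 0.10 after array medians were subtracted, which moved the median of all rows from 0.01 to 0.16; its call was lost without Het LSK replicate 1 (adjusted p = 0.0944) or Het GMP replicate 1 (0.152).

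In the knockout, fewer rows differed between GMP and LSK: 1318, of which 797 were higher and 521 lower in GMP. Atp8b4 was higher in GMP by 5.41 (9.44 ± 0.18 against 4.03 ± 0.17, adjusted p = 3.32e-06), Clec12a by 4.96, the eosinophil granule gene Prg2 by 4.78, B4galt6 by 4.73 and Ms4a3 by 4.68. Atp8b4 and B4galt6 differed between KO and Het by -3.65 and -2.67 in LSK and by -0.89 and -0.56 in GMP. Their lower level in KO LSK thus widened this separation. Granulocyte genes still separated the cells. Of 20 primary granule genes, 15 were higher and 0 lower (16 and 0 adjusted over the list alone; median 2.86; adjusted p = 5.18e-29, and adjusted p = 0.0551 with an estimated correlation), among them Hp, by 4.26. Gimap4 (-4.27), Cd200r3 (-3.10), Cd200r4 (-3.00), Stxbp4 (-2.86) and P2rx7 (-2.61) were lower in KO GMP, the last without a call when KO GMP replicate 2 was left out (adjusted p = 0.102) and at -1.72 without KO LSK replicate 1. Stem cell genes were lower for 11 and higher for 2 of 27 (15 and 2 adjusted over the list alone; median -0.71; adjusted p = 1.92e-06, and adjusted p = 0.506 with an estimated correlation), and lymphoid priming genes lower for 3 of 26 (4 adjusted over the list alone; median -0.33; adjusted p = 0.00257, and adjusted p = 0.506 with an estimated correlation). This lymphoid call was lost without KO LSK replicate 1 (adjusted p = 0.228). Of 20 megakaryocyte genes, 6 were higher and 0 lower (7 and 1 adjusted over the list alone; median 0.16, and 0.072 after another quantile normalization; adjusted p = 0.00745, and adjusted p = 0.528 with an estimated correlation), where 11 had been lower in Het GMP; this call was lost without KO LSK replicate 2 (adjusted p = 0.292). The preset correlation called 14 lists, 7 each way; the estimated one called 0 (1 at an unadjusted p under 0.05) and fry 3. The count of rows was 579 without KO GMP replicate 1, 616 without KO GMP replicate 2, 691 in a fit of the 2 groups alone and 756 when all rows of the table were tested. That fewer rows passed than in the control was not tested as a difference between counts; the interaction above is the test per row.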

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

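All tests of explanations below were chosen after the results were seen; the tests of the interaction between genotype and cell type were planned. By that test the effect of Cbfb loss differed between GMP and LSK for 499 rows, which is why the following genes and lists stand here. Differences are the log2 effect in GMP minus that in LSK.

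Of these rows, only the genes named in the text are given. Among them, the largest positive differences were those of Dntt (5.47), Ccl3 (4.30), Wfdc17 (4.27), Il7r (3.86), Pdzk1ip1 (3.71), Mmrn1 (3.61), Pf4 (3.48), Ebf1 (3.34), Vpreb3 (3.29), Cd79a (3.11), Prkcq (2.90), Lsp1 (2.86), Gimap6 (2.83), Egr1 (2.77), Atp8b4 (2.76) and Car2 (2.65). Smaller ones were found for Thy1 (2.61), Meis1 (2.52), Flt3 (2.51), Mecom (2.39), Klrd1 (2.36), Emb (2.33), Zfpm1 (2.32), Mtss2 (2.18), Lat (2.15), Nkg7 (2.14), F2r (2.13), Procr (2.12), B4galt6 (2.11), Foxo1 (2.04), Cd72 (2.0) and Ifit3 (1.99). The smallest of the named ones were those of Cish (1.91), Bgn (1.87), Emcn (1.86), Ppbp (1.80), Rtp4 (1.79), Cd74 (1.77), S1pr1 (1.76), Dpp4 (1.67), Iigp1 (1.64), Pdgfrb (1.60), Itga2b (1.60), Gp5 (1.45), Gata1 (1.41), Trp53inp1 (1.40), Notch1 (1.08) and Ccnd1 (0.83). The effect was more positive in LSK for Prss34 (-1.08), Catspere2 (-1.25), Epx (-1.25), Fkbp1b (-1.53), Sorl1 (-1.77), Cst7 (-1.80), Fcgr3 (-1.84), Hdc (-1.91), Cxcr2 (-1.93) and Gimap4 (-2.01). It was also more positive there for Tifab (-2.03), Chd7 (-2.09), Met (-2.35), Ms4a2 (-2.41), Fgf10 (-2.43) and Cd200r4 (-2.50). Aoah (-2.74), Gpr141 (-2.80), Cpa3 (-2.99), Ly6a2 (-3.24) and Cd200r3 (-3.41) followed. Aoah, Gpr141 and Ly6a2 lay below the median of the tested rows in Het LSK, with little room to fall there. Leaving out Het LSK replicate 1 ended the interaction calls, with the adjusted p in parentheses, of Ly6a2 (0.052), Gata1 (0.059), Epx (0.0724), Ccnd1 (0.121), Rtp4 (0.0655), Flt3 (0.0513), S1pr1 (0.0719), Itga2b (0.0552), Mtss2 (0.0946), Fcgr3 (0.0704) and Prss34 (0.0612). Mecom (0.0588), Gata1 (0.0986), Cxcr2 (0.058), Pdgfrb (0.0955), Ccnd1 (0.143), Flt3 (0.0658), S1pr1 (0.159), Itga2b (0.095), Mtss2 (0.15), Met (0.0554), Notch1 (0.0981) and Ppbp (0.0856) lost them without Het LSK replicate 2. Without KO LSK replicate 1, those of Ly6a2 (0.0786), Cd74 (0.0759), Hdc (0.0634), Ccnd1 (0.0661) and Fcgr3 (0.0815) ended. Ly6a2 (0.0777), Gata1 (0.0578), Cd74 (0.0755), Hdc (0.0861), Ccnd1 (0.091), Rtp4 (0.0625), S1pr1 (0.106), Itga2b (0.0578), Mtss2 (0.0971), Notch1 (0.0596), Fcgr3 (0.0655) and Ppbp (0.0512) were not called without KO LSK replicate 2. Those lost without Het GMP replicate 1 were Ly6a2 (0.142), Mecom (0.0634), Procr (0.0646), Cxcr2 (0.0844), Cd74 (0.166), Hdc (0.116), Epx (0.099), Pdgfrb (0.107), Ccnd1 (0.19), Flt3 (0.0729), Cish (0.0512), S1pr1 (0.0761), Fgf10 (0.0553), Gp5 (0.0615), Itga2b (0.0611), Notch1 (0.115), Fcgr3 (0.139) and Prss34 (0.0648). The fit without Het GMP replicate 2 did not call Ly6a2 (0.158), Mecom (0.0631), Gata1 (0.0872), Cxcr2 (0.0875), Cd74 (0.133), Hdc (0.148), Pdgfrb (0.067), Ccnd1 (0.0806), Rtp4 (0.085), Iigp1 (0.0558), Fgf10 (0.0532), Gp5 (0.0657), Mtss2 (0.076), Met (0.0618), Notch1 (0.0727), Fcgr3 (0.163) and Prss34 (0.0873). In the fit without KO GMP replicate 1, Procr (0.0506), Cd74 (0.0887), Hdc (0.0851), Epx (0.0619), Pdgfrb (0.0633), Ccnd1 (0.107), Rtp4 (0.0934), S1pr1 (0.114), Mtss2 (0.0886), Notch1 (0.0947), Fcgr3 (0.0648) and Ppbp (0.0721) did not pass. Omitting KO GMP replicate 2 removed the calls of Ly6a2 (0.149), Mecom (0.0532), Gata1 (0.0908), Cxcr2 (0.0846), Cd74 (0.157), Hdc (0.147), Epx (0.101), Pdgfrb (0.0949), Ccnd1 (0.184), Rtp4 (0.0731), S1pr1 (0.148), Gp5 (0.0549), Itga2b (0.0922), Mtss2 (0.15), Fcgr3 (0.162), Ppbp (0.0547) and Prss34 (0.0878).

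Among the gene lists, the median difference was 1.57 for lymphoid priming, 1.45 for megakaryocyte and platelet, 1.07 for stem cell, 0.83 for interferon response, 0.66 for B cell, 0.58 for erythroid and 0.40 for T and NK cell genes. It was 0.35 for hematopoietic transcription factors, 0.33 for p53 response, 0.25 for immediate early and heat shock, 0.21 for Hox, 0.17 for RUNX target and 0.15 for cytokine receptor genes. After array medians were subtracted, the T and NK cell median was 0.26, that of transcription factors 0.21, p53 response 0.19, immediate early and heat shock 0.11, Hox 0.07, RUNX target 0.03 and cytokine receptor genes 0.01, so their size depends on the scaling. For ribosome biogenesis it was -0.17 as deposited and -0.31 after the subtraction, with 0 members passing limma's test (1 lower at an unadjusted p under 0.05), and for mast cell, basophil and eosinophil genes -0.30. The ribosome biogenesis call was lost without Het LSK replicate 2 (adjusted p = 0.15), KO LSK replicate 2 (0.192) or Het GMP replicate 1 (0.198), and the cytokine receptor call without KO LSK replicate 2 (0.0925). With an estimated correlation 0 of these lists were called (6 at an unadjusted p under 0.05).

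Signals also appeared in rows that no comparison of the report used. Of the 12146 rows with no gene symbol, 204 passed in LSK (73 higher and 131 lower in KO) and 89 in GMP (53 and 36), adjusted over all 35556 rows. Of the 1621 rows with several symbols, 43 passed in LSK (12 and 31) and 14 in GMP (9 and 5).

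Megakaryocyte and platelet genes were higher in KO GMP, 17 of 20 past the threshold. KO LSK cells among the sorted KO GMP cells would leave these genes well below their KO LSK level, but over the 17 genes KO GMP lay above KO LSK by a median of 0.18, while primary granule genes differed between KO and Het GMP by a median of only -0.21; this argues against that explanation. Platelets or mature megakaryocytes in the sort stay open: Pf4 and Ppbp rose (2.23 and 2.30), but Tubb1, an abundant platelet gene, differed by 0.35 without passing (adjusted p = 0.552). Erythroid and megakaryocyte progenitors inside the GMP gate also stay open. The erythroid list rose with a median of 0.49 although Car1 fell, a rise called with the preset correlation and not with an estimated one. No sorted megakaryocyte or erythroid progenitors were analysed here. A direct effect of Cbfb loss on these genes within GMP, the difference the design names, was not tested apart from these.

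Lymphoid priming genes were lower in KO LSK, 20 of 26 past the threshold with a list median of -1.59. Mature B cells in the Het sort stay open: Cd79b (-0.81), Cd22 (-0.48), Ms4a1 (0.00) and Ighm (0.98) had a median of -0.24, but Ighm (4.89), Cd22 (3.94) and Ms4a1 (2.66) lay below the median of the tested rows in Het LSK (5.08), with little room to fall, and Cd79b, at 8.48, fell (adjusted p = 0.00724). The LSK gate excludes cells with lineage markers and the design text gives a purity above 98%, but no B cells were measured to set how many such levels allow. Under the other scalings the list median was at most -1.50 and 20 members passed. The fall thus does not depend on which of these scalings is used. They could hardly have changed it, since RMA had already normalized the arrays. Subtraction of array medians moved the median of all rows in LSK only from 0.01 to 0.10. Fewer lymphoid-primed cells among KO LSK stay open: the fallen members varied widely (interquartile range 2.08) and none rose, so a loss of such cells and lower expression within cells cannot be told apart without single cells.

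Runx1 was higher in KO in both cell types (1.53 and 1.47). Under the other scalings its lowest change was 1.42, with limma's adjusted p of at most 0.00153. The rise thus does not depend on which of these scalings is used, though they could hardly have changed it either. Hybridisation of Runx3 RNA to the Runx1 probes is argued against. The change of Runx1 exceeded that of Runx3 by at least 0.97, against a bound of 0.55 from their standard errors. Runx2 was not analysed here. Another mix of cells inside the gates stays open, because no other sorted population was measured; neither Het population reached the KO level, since the lowest KO mean lay 1.08 above the highest Het mean. A response of Runx1 to the loss of its partner is a hypothesis that may hold beside it, and these data do not decide it.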

How the results depend on the processing

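The alternatives were planned except the use of 1 row per gene, which was chosen after the data were seen. The values counted next are those of all genes that the rule took or the text names, with or without a call. A value that stayed uncalled counts as kept. In LSK 3001 of 3164 kept their direction and their side of the threshold, 122 lost and 27 gained a call. In GMP 2840 of 3059 kept both, 147 lost and 56 gained one. For the interaction 2792 of 3100 kept both (204 lost, 63 gained), between GMP and LSK in Het 3453 of 3645 (147, 30) and in KO 3475 of 3754 (159, 75). Counts stayed within 1.5 times of the reported one in 18 of 22 alternatives for LSK, 16 of 22 for GMP, 15 of 22 for the interaction, 19 of 23 for GMP against LSK in Het, 17 of 23 in KO and 15 of 21 for the overlap.

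The other counts came from construction in part: a fold minimum removes small changes, a left-out array removes degrees of freedom, and all rows of the table enlarge the adjustment and change the variance estimate. A 2-fold minimum gave 731 rows in LSK, 620 in GMP, 1348 and 520 for GMP against LSK in Het and in KO, and 268 shared by LSK and GMP in the same direction. An adjusted p threshold of 0.10 gave 847 for the interaction and 2041 for GMP against LSK in KO. A fit of the 2 groups alone gave 1071 in LSK and 691 for GMP against LSK in KO. It gave more rows than reported in GMP (1539) and for GMP against LSK in Het (4122). Array weights gave 1256 in LSK and 1940 in GMP. Which cell type had more called rows thus depends on how the spread is estimated. Testing all rows of the table gave 784 in GMP, 182 for the interaction, 756 for GMP against LSK in KO and 324 in the overlap. One row per gene gave 1585, 1255, 461, 3521 and 1228 for LSK, GMP, the interaction, and GMP against LSK in Het and in KO, and another quantile normalization 1618, 1180, 409, 3656 and 1240.

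Leaving out 1 array gave 994 to 1614 rows in LSK, 634 to 1586 in GMP, 223 to 705 for the interaction, 2078 to 4486 for GMP against LSK in Het, 579 to 1539 in KO, and 321 to 637 in the overlap. The remaining array of such a group is assumed to vary like those of the other groups. Called lists numbered 7 to 10 in LSK and 11 to 13 in GMP. An estimated correlation gave 0 lists in each by limma's camera (3 and 4 at an unadjusted p under 0.05; limma's fry called 6 and 8), and a filter at the 50th percentile of intensity gave 5 lists in LSK; the cause of either was not tested.

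Sign changed only for values that passed neither as reported nor under the alternative: 14 in LSK, 16 in GMP, 41 for the interaction, and 15 and 45 between GMP and LSK in Het and in KO. Leaving out 1 array gave both signs in LSK for Aurkb (-0.64 to 0.24), Cbfa2t3 (-0.054 to 0.41), Elane (-0.64 to 0.39), Gimap6 (-0.43 to 0.078), Ms4a3 (-0.44 to 0.076), Prg2 (-2.16 to 0.064), Trp53inp1 (-0.052 to 0.24), Tubb1 (-0.49 to 0.33) and Zfpm1 (-0.12 to 0.14). It did so in GMP for Cd79a (-0.0085 to 0.14), Cenpf (-0.062 to 0.067), Dntt (-0.067 to 0.62), Ebf1 (-0.24 to 0.084), Hoxa5 (-0.11 to 0.38), Klrd1 (-0.31 to 0.29), P2rx7 (-0.39 to 0.35), Prg2 (-0.24 to 0.13), Procr (-0.32 to 0.040) and Runx1t1 (-0.095 to 0.26). It did so in the interaction for Aurkb (-0.79 to 0.087), B3gnt5 (-0.032 to 0.62), Elane (-0.60 to 0.43), H2-Aa (-0.41 to 0.19), Hp (-0.28 to 0.41), Il4 (-0.69 to 0.026), Kcnj5 (-0.53 to 0.44), Klf2 (-0.16 to 0.13), Mcpt8 (-0.62 to 0.33), Mgam (-0.21 to 0.19), Pbx3 (-0.11 to 0.38), Prg2 (-0.12 to 2.10), Retnlg (-0.78 to 0.87), Runx1 (-0.30 to 0.18) and Stxbp4 (-0.19 to 0.46). It did so between GMP and LSK in Het for B3gnt5 (-0.35 to 0.032), Cbfb (-0.030 to 0.090), Kcnj5 (-0.38 to 0.27), Kcnk9 (-0.10 to 0.55), Ppbp (-0.49 to 0.22), Retnlg (-0.65 to 1.00) and Tubb1 (-0.12 to 0.063). It did so between GMP and LSK in KO for Ak4 (-0.40 to 0.56), Aoah (-0.028 to 0.78), Aurkb (-0.00028 to 0.88), B3gnt5 (-0.19 to 0.46), Bgn (-0.24 to 0.041), Car1 (-0.85 to 0.28), Cbfa2t2 (-0.046 to 0.019), Cbfb (-0.47 to 0.0080), Cd72 (-0.15 to 0.067), Cdkn2a (-0.66 to 0.14), Cenpf (-0.17 to 0.77), Clca3a1 (-0.12 to 0.80), Dpp4 (-0.26 to 0.15), Fkbp1b (-0.015 to 0.26), Ighm (-2.71 to 0.24), Il7r (-0.50 to 0.46), Irf8 (-0.43 to 0.32), Itga2b (-0.0088 to 0.29), Kcnj5 (-0.58 to 0.38), Ly86 (-0.25 to 1.93), Met (-0.078 to 0.68), Mmrn1 (-0.16 to 0.12), Notch1 (-0.13 to 0.12), Pdgfrb (-0.44 to 0.14), Runx1t1 (-0.034 to 0.097), S1pr3 (-0.39 to 0.25), Sorl1 (-0.0048 to 0.43), Thy1 (-0.072 to 0.75), Tifab (-0.22 to 0.17), Treml1 (-0.38 to 0.31) and Tubb1 (-0.0068 to 0.81). Another quantile normalization changed the sign in GMP for Prg2 (0.069), in the interaction for Runx1 (0.016), Mgam (0.024), Pbx3 (-0.057) and Retnlg (-0.090), between GMP and LSK in Het for Cbfb (-0.032), Kcnj5 (0.0069) and Tubb1 (0.080), and between GMP and LSK in KO for Dpp4 (0.0024). Subtraction of array medians changed it in LSK for Tubb1 (0.0052), in GMP for Cenpf (-0.048), in the interaction for Stxbp4 (-0.0013), Hp (-0.074), Pbx3 (-0.0040) and Retnlg (-0.096), between GMP and LSK in Het for Kcnj5 (0.10), Tubb1 (0.13) and Ppbp (0.019), and between GMP and LSK in KO for Cbfa2t2 (0.0042) and Notch1 (0.0092). The cause was not tested.

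Cbfb in LSK (-0.60) passed under filters at the 50th (adjusted p = 0.0346) and 25th percentile (0.0452), with an intensity trend (0.0352), with a trend and robust fitting (0.0325), and without either KO GMP array (0.0252); the filters leave fewer rows to adjust over, and for the others the cause was not tested. Leaving out 1 array gave -0.63 to -0.58. In GMP it stayed at -0.86 without passing when all rows were tested (adjusted p = 0.0632), and leaving out 1 array gave -1.10 to -0.63, without a call in the absence of Het GMP replicate 1 (0.0689) or 2 (0.104) or KO GMP replicate 1 (0.0755).

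The labels give the groups the same replicate numbers without saying that a number marks a mouse. Deviations of same-numbered arrays from their group means correlated at 0.133 (Het LSK and Het GMP), 0.179 (KO LSK and KO GMP), -0.143 (Het LSK and KO LSK), -0.0255 (Het GMP and KO GMP), -0.0411 (Het LSK and KO GMP) and -0.0679 (KO LSK and Het GMP). Only the pairs of the same genotype were positive, the direction that shared mice would give. These values are small and do not settle whether a number marks a mouse. The reported tests pair no arrays, and the blocks below show what pairing changes. With the replicate number as a block, 1570 rows passed in LSK, 1224 in GMP, 480 for the interaction, 3602 for GMP against LSK in Het and 1216 in KO, and 559 in the overlap, with 9 and 12 lists. With genotype and number together as a random block (consensus correlation 0.139) the counts were 1685, 1323, 719, 4411 and 1698, and as a fixed block 635, 4162 and 1499 for the last 3. The signal over background limits dim genes: RMA marks none as undetected, and their folds are understated.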

Other observations

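The immediate early genes, which respond within minutes to growth signals and stress, and the heat shock genes, which respond to damaged proteins, were fixed as 1 list and are split here after their values were seen. Of the 17 immediate early genes, 12 rose in KO GMP and 3 in KO LSK (median 0.87 and 0.47). Of the 6 heat shock genes, 0 rose or fell in either by limma's test, with a median of 0.02 in GMP (from -0.83 to 0.31) and 0.10 in LSK.

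The mast cell, basophil and eosinophil list was not called in GMP (adjusted p = 0.26), and its single genes changed as follows. The eosinophil peroxidase gene Epx fell by 1.58 (SE 0.16, adjusted p = 0.00046) and the basophil protease gene Prss34 fell by 1.49 (SE 0.13, adjusted p = 0.000204), with Ms4a2 and Mcpt8. The eosinophil granule genes Prg2 (-0.06, adjusted p = 0.979) and Prg3 (0.50, adjusted p = 0.0931) did not pass, and Il4, a cytokine gene of basophils and mast cells, rose by 1.07 (adjusted p = 0.0152), a call that was lost without KO GMP replicate 1 (0.0833) or 2 (0.0976). In KO LSK, Il4 rose by 1.41 and Cpa3 by 3.92. Chd7, which encodes a chromatin remodelling enzyme and was chosen after its values were seen, is represented by 30 rows. Of these, 29 rose in KO LSK, and the 30 rows differed by 0.63 to 3.47; in GMP 9 rose, with differences of 0.37 to 0.89. Its row with the highest mean rose by 2.72 in LSK (adjusted p = 3.1e-05) and differed by 0.63 in GMP (adjusted p = 0.0566, and 0.0465 without either KO LSK array), and the effect was larger in LSK (interaction -2.09, adjusted p = 0.003).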
